A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

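Expression was measured on 24 Affymetrix Yeast Array 2.0 arrays, each hybridized with biotin-labelled cRNA made from 5 ug of total RNA of Saccharomyces cerevisiae. The 24 arrays cover 4 strains: the wild type BY4741, deletions of pbf1 and of pbf2, and the double deletion. Per the labels, each strain was grown at 25 °C in 3 cultures, and each culture was divided into a part collected at 0 min and a part collected after 20 min at 37 °C. The 8 groups of strain and time therefore hold 3 arrays each, and the replicates are cultures.

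The deposited values are intensity values on a linear scale, 1 per probe set and array, made by the authors with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. The authors' accompanying text names GeneChip Operating Software 1.4 for image extraction. Tested on the deposited values, the mean signal of all 10928 probe sets with 2% trimmed on each side lay between 500.3 and 500.4 on every array. The authors' deposited table of expression ratios holds log2 ratios of 20 min over 0 min per strain and a false discovery rate, a p-value type of column per the file headers, made with the GoldenSpike method. Only its wild type rate was used, since the columns of the 3 deletions share 1 name. Image files were not used here.

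Of the probe sets, 7244 carry 1 gene name, 1 carries several and 3683 carry none, 213 of them controls. Of the named probe sets, 5498 name a gene of the S. cerevisiae table, and 1746 name genes outside it and served as the background. For the 47 genes with more than 1 probe set, the probe set with the highest mean was taken, which left 5449 genes. The reference gene table (S. cerevisiae R64) was used for names and neighbours only, and updated 12 symbols. The deposited values name no genome build, so no coordinates are given. A gene was tested when its mean log2 signal over all arrays exceeded 2.35, the 90th percentile of the outside probe sets, a signal of 5.09. This kept 5395 genes and left out 54. On each array a signal above the 95th percentile of the outside probe sets, 9.02 to 11.6 depending on the array, counted as above background: 5183 genes were above it on every array and 18 on none. No counts exist for arrays, so the number of arrays limits the precision.

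The deposited signals were put on the log2 scale without a pseudocount and without a further scaling. All 24 arrays were fitted together with limma 3.58.1 in R 4.3.3 as 8 group means (lmFit, contrasts, eBayes with trend, 16 residual degrees of freedom). P-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested within each comparison, with a threshold of 0.05. The comparisons were heat shock within each strain, the difference in heat shock response between strains (an interaction contrast), the departure of the double deletion from the sum of the single deletions on the log2 scale, and the strain differences at 0 min and at 20 min. Changes are log2 ± the standard error of limma. Preparation and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

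Before the data were examined, 27 gene lists, the comparisons, the tests, the rule for naming genes and most alternatives were fixed. The lists cover ribosome biogenesis, RNA polymerase I and III, cytosolic and mitochondrial ribosomal proteins, chaperones and heat shock proteins, genes induced by environmental stress, trehalose and glycogen metabolism, the proteasome, translation factors, aminoacyl tRNA synthetases, tRNA modification and processing, purine and pyrimidine synthesis, amino acid synthesis, sulfur assimilation and methionine, glycolysis, the TCA cycle and respiration, cell wall integrity, ergosterol synthesis, the cell cycle, the phosphate and iron response, a-cell, alpha-cell, haploid and pheromone genes, sporulation and diploid genes, stationary phase genes, auxotrophic marker genes and neighbours of the deleted genes. They hold 1034 genes with a probe set, 29 of them in more than 1 list. The 26 lists with at least 5 tested genes were tested with camera, once with a preset correlation of 0.01 and once with an estimated correlation, and with fry, each adjusted over the 26 lists of a comparison. Camera compares a list with the other genes. Fry tests whether a list's genes move, on balance, one way, and compares them with no other genes. Alpha-cell genes have 4 members and were not tested as a list. The median response of 2 lists per culture was compared between each deletion and the wild type with a two-sided exact permutation test, which cannot go below 0.1 with 3 cultures against 3.

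Genes were named by rule. TOD6 and DOT6 were always named. Named by size among genes past the threshold were the 10 largest rises and 10 largest falls of the wild type heat shock, 5 and 5 in each deletion, 12 and 12 of the response difference of the double deletion, 6 and 6 of the other response differences, and 5 and 5 of each strain difference. For heat shock, the 3 same-numbered pairs of arrays had to share the sign. From each list the 2 largest rises and 2 largest falls were named for the wild type heat shock and for the response difference of the double deletion, with the marker, mating-type and neighbour genes. As an exception made after the data were seen, only genes above background on at least 1 array of every group compared were ranked, which skipped 41 genes in the wild type heat shock and 8 in the response difference of the double deletion. Where a named gene is given in a comparison other than the one that named it, it was chosen as an example after its values were seen. For TOD6, DOT6 and URA3, a comparison with a group at background on every array is given as a bound, the geometric mean of the brighter group over the background of the dimmer group's arrays.

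Alternatives kept every other choice: quantile normalization, centring of each array on the median S. cerevisiae probe set, a pseudocount of 50, no filter, a stricter filter at a mean log2 of 9.04, eBayes without trend, fits of only the groups compared, the culture or the replicate number as a block, lists without shared members, and each array left out in turn. Added after the data were seen were centring on the poly(A) spike-in controls or on the hybridization controls, the replicate number within each time as a block, probe sets marked as shared left out, and list tests with each array left out. Overlaps of strain differences that share the wild type arrays were set beside 100 simulated draws with unchanged groups. Simulated data were drawn as independent normal noise of each gene's spread around the wild type means at 0 min. On these, the test of the response difference of the double deletion called 31 of 67 genes given a log2 change of 0.5 (46.3%), 58 of 67 at 1 (86.6%) and 62 of 66 at 2 (93.9%), with 7 false calls. Such noise leaves out the similarity of equal replicate numbers seen in the arrays, so the real rates may differ. Within groups, log2 values of replicate arrays correlated with r between 0.980 and 0.995 across genes, and no gene had the same value on a pair of replicate arrays. Residuals of the 0 min and 20 min arrays of a culture correlated with a median r of 0.057 (-0.041 to 0.186), and the consensus correlation within cultures was 0.0709, so the culture was kept as an alternative block only.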

Results

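Messenger RNA levels of 5395 yeast genes were measured on 24 arrays before and after a heat shock from 25 °C to 37 °C for 20 min. The 4 strains were the wild type BY4741, deletions of pbf1 (TOD6, YBL054W) and of pbf2 (DOT6, YER088C), and the double deletion, each with 3 cultures at 0 min and at 20 min. TOD6 and DOT6 encode related Myb-type repressors that bind the PAC motif found upstream of many ribosome biogenesis genes. The series asks about the DNA binding of yeast transcription factors, and the arrays address which heat shock changes depend on these factors. The median signal of the S. cerevisiae probe sets ranged from 453 to 572 over the arrays, and that of the probe sets outside S. cerevisiae from 1.67 to 2.50. Between 96.7% and 99.1% of the genes were above background on each array.

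The deleted genes were at background where they should be absent, except for DOT6 on 1 array. TOD6 had a geometric mean signal of 455 in the wild type at 0 min and 162 at 20 min. It was at least 43.7-fold lower in the pbf1 deletion and at least 43.0-fold lower in the double deletion at 0 min, and at least 15.5-fold and 15.7-fold lower at 20 min. DOT6 had a signal of 855 in the wild type at 0 min and 889 at 20 min. It was at least 83.8-fold lower in the pbf2 deletion at 0 min and at least 98.0-fold lower at 20 min, and at least 86.1-fold lower in the double deletion at 20 min. In the double deletion at 0 min DOT6 had a signal of 8.85, with 1 array above background. URA3, an enzyme gene of uracil synthesis, was at background in the wild type and both single deletions and had a signal of 1789 in the double deletion at 0 min, at least 177-fold above the wild type, and 815 at 20 min, at least 82.0-fold above it. Neither TOD6 (YBL054W, log2 -1.49 ± 0.87 (SE), adjusted p = 0.121) nor DOT6 (YER088C, log2 0.06 ± 0.54, adjusted p = 0.925) passed the threshold for heat shock in the wild type. These standard errors pool the spread of all groups, including the deletions where the genes lie at background. They need not measure the spread in the wild type, so these tests cannot show that the genes did not respond.

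**Figure D1:**
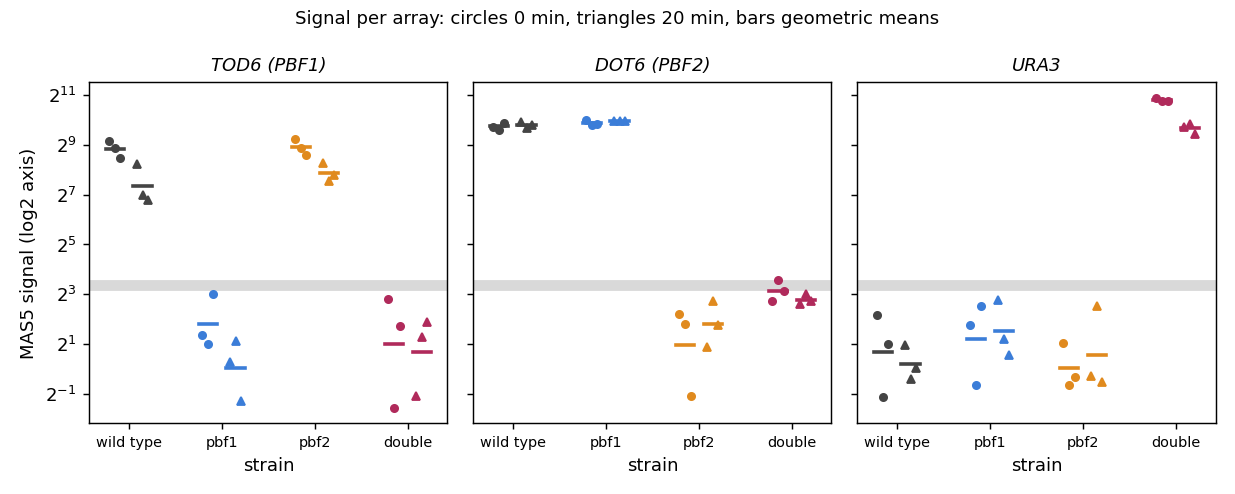
Signal of TOD6, DOT6 and URA3 on each array (log axis), with circles for 0 min, triangles for 20 min and bars for the geometric mean of 3 cultures. The grey band is the background of the arrays, 9.02 to 11.6, and URA3 stands above it in the double deletion alone.

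Heat shock in the wild type raised stress, chaperone and carbohydrate reserve genes and lowered the genes of ribosome production. The largest rises were HXT5 (YHR096C, log2 6.80 ± 0.14, adjusted p = 1.47e-19), a hexose transporter, HSP12 (YFL014W, 6.44 ± 0.10), a membrane-associated heat shock protein, FMP45 (YDL222C, 6.35 ± 0.18), and HSP26 (YBR072W, 6.31 ± 0.14), a small heat shock protein. ARO10 (YDR380W, 6.17), LSO1 (YJR005C-A, 6.12), ALD3 (YMR169C, 6.09), DDR2 (YOL052C-A, 5.97) and the Hsp70 genes SSA3 (YBL075C, 5.93) and SSA4 (YER103W, 5.53) followed. The largest falls were HO (-4.16 ± 0.19, adjusted p = 3.49e-14), the mating-type endonuclease, YHB1 (YGR234W, -3.92 ± 0.15), a flavohemoglobin, RPS26B (YER131W, -3.83 ± 0.21) and RKI1 (YOR095C, -3.81 ± 0.22). KRE33 (YNL132W, -3.74), RPS0B (YLR048W, -3.72), AAH1 (YNL141W, -3.64), NOP13 (YNL175C, -3.62), NOP7 (YGR103W, -3.58) and RPL9A (YGL147C, -3.54) followed, most of them ribosomal proteins or factors that assemble ribosomes.

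Of 5395 genes, 2752 rose and 1600 fell in the wild type, of which 1070 rose and 697 fell at least 2-fold. The share of rises depended on the scaling: 2171 rose and 2015 fell after quantile normalization, 2305 and 1976 after median centring, 1766 and 2020 after centring on the hybridization controls, and 313 and 2177 after centring on the poly(A) spike-in controls. The median change of all genes was 0.27 (log2) as scaled by the authors, and 0.04, 0.08, -0.04 and -0.74 under these scalings in the same order. In the authors' deposited table, 1614 probe sets were higher and 1516 lower at a false discovery rate of at most 0.0001, and its log2 ratios correlated with the fitted changes with r = 0.979 across genes, which are not independent replicates.

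Ribosome biogenesis genes fell as a group in the wild type: 160 of 164 fell, 2 rose and 2 did not pass, with a median log2 change of -1.88 (camera adjusted p = 2.21e-33, and 0.154 with an estimated correlation). HMO1 (YDR174W, 0.21) and LAS1 (YKR063C, 0.20) were the 2 that rose. Of 127 cytosolic ribosomal protein genes, 126 fell, among them RPS26B, and RPL15B rose by 1.30 (median -1.88, adjusted p = 2.9e-39, and 0.0824 with an estimated correlation). RNA polymerase I and III genes had 26 falls, such as RPA190 (YOR341W, -3.33) and RPA135 (YPR010C, -3.18), and 5 rises, such as TFC7 (YOR110W, 0.54), among 39. All 21 aminoacyl tRNA synthetase genes fell (median -1.59), CDC60 by -2.61, and 34 of 37 translation factor genes fell, TIF3 by -2.74, with 3 not passing. Of 48 tRNA modification and processing genes, 38 fell, TRM1 by -2.95, and 3 rose. Of 29 purine and pyrimidine synthesis genes, 20 fell, URA7 by -3.14, and 6 rose, ADE17 by 2.77. Of 58 amino acid synthesis genes, 36 fell, ARO4 by -3.28, and 15 rose, ARG3 by 3.64. Of 25 ergosterol synthesis genes, 21 fell, NCP1 by -1.39, and 2 rose. Of 36 cell cycle genes, 20 fell, CLN2 by -2.48, and 3 rose. Counts adjusted over the list alone were the same for all of these lists. None of their camera calls passed with an estimated correlation (adjusted p between 0.0701 and 0.17).

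All 93 genes of the environmental stress list rose (median 2.61, adjusted p = 1.02e-17, and 0.154 with an estimated correlation), as did all 16 stationary phase genes (median 2.47). Of 42 chaperone and heat shock genes, 37 rose and 4 fell, among them the cochaperones CNS1 (YBR155W, -1.11) and MGE1 (YOR232W, -0.80). Of 21 trehalose and glycogen genes, 19 rose, GPH1 by 5.14, and PGM1 fell by 1.36. Of 42 proteasome genes, 40 rose, NAS2 by 1.49, and POC4 fell by 1.12. Of 48 genes of the TCA cycle and respiration, 38 rose, CYC7 by 4.48, and 3 fell, and of 66 genes of the mitochondrial ribosomal protein list, 52 rose and 3 fell. The medians of the proteasome (0.73), respiration (0.71) and mitochondrial ribosomal (0.48) lists became negative after spike-in centring and stayed positive under the other scalings. Adjusted over the list alone, the counts were the same, and no camera call held with an estimated correlation (adjusted p between 0.0701 and 0.253).

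Smaller groups went both ways. Of 28 sulfur and methionine genes, 13 rose, STR3 by 4.01, and 10 fell, SAM1 by -2.08, with a median of 0.09 and a mean of 0.52 while camera ranked the list downward (adjusted p = 0.878). Of 20 glycolysis genes, 8 rose (7 adjusted over the list alone), HXK1 by 3.06, and 3 fell, with a median of 0.09 that, like that of the sulfur list, was negative after median, spike-in and hybridization control centring. Of 24 cell wall integrity genes, 13 rose, PIR3 by 5.20, and 7 fell, SVS1 by -2.88, with a median of 0.61 that was negative after spike-in centring. Of 23 phosphate and iron genes, 9 rose, HMX1 by 2.85, and 11 fell, PHO5 by -2.39. Of 18 sporulation genes, 11 rose, DMC1 by 3.13, and SPS4 fell by 1.21, with a median of 0.95 that was negative after quantile normalization and spike-in centring. Camera called none of these lists. Mating genes fell: 6 of 7 a-cell genes, AGA2 by -3.01 (list adjusted p = 0.00219, and 0.178 with an estimated correlation), and 10 of 14 haploid and pheromone genes, FAR1 by -2.48, with 3 rises, RME1 by 1.32 (adjusted p = 0.0111, and 0.198 with an estimated correlation). Of the alpha-cell genes, STE3 rose by 1.75 and SAG1 by 0.38, and MF(ALPHA)1 fell to background on every array (adjusted p = 0.0304). Among 6 auxotrophic marker genes, ADE2 rose by 1.59 and LYS2 fell by 0.89. MET17 passed the threshold upward from background (adjusted p = 0.0126), which does not show that the gene is expressed. The median (-0.30) and mean (0.21) of the marker list differed in sign (adjusted p = 0.736). Of 8 neighbours of the deleted genes, 2 rose and 3 fell (2 and 2 adjusted over the list alone; adjusted p = 0.396).

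The single deletions responded to heat shock much like the wild type, and the double deletion less so. In the pbf1 deletion 2763 genes rose and 1640 fell, led by HXT5 (6.70), HSP12 (6.52), HSP26 (6.42), ALD3 (6.41) and FMP45 (6.23), and by HO (-4.07), AAH1 (-3.95), YHB1 (-3.93), MIS1 (YBR084W, -3.85) and INA1 (YLR413W, -3.83). In the pbf2 deletion 2611 rose and 1624 fell, led by HXT5 (6.70), ALD3 (6.51), ARO10 (6.37), HSP12 (6.34) and FMP45 (6.22), and by HO (-4.24), the helicase gene DBP2 (YNL112W, -4.13), YHB1 (-3.80), INA1 (-3.64) and the cyclin gene CLB6 (YGR109C, -3.47). In the double deletion 2615 rose and 1667 fell, led by HSP12 (7.37), TMA10 (YLR327C, 6.97), HSP26 (6.89), DDR2 (6.83) and HXT5 (6.49), and by INA1 (-4.65), PLB2 (YMR006C, -4.37), RPL13A (YDL082W, -4.10), RPS0B (-4.03) and RPS26B (-4.02). After quantile normalization the rises and falls were 2157 and 2085, 2023 and 2111, and 2001 and 2194 in these 3 strains. They were 2272 and 2032, 2069 and 2068, and 1977 and 2281 after median centring. After hybridization control centring they were 1894 and 1990, 1727 and 1926, and 1785 and 2074, and after spike-in centring 262 and 2801, 342 and 1543, and 280 and 2722.

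Across genes, which are not independent replicates, the response of the wild type correlated with that of the pbf1 deletion with r = 0.985 (Spearman 0.983), of the pbf2 deletion with r = 0.973 (0.971) and of the double deletion with r = 0.904 (0.904). Of 3791 genes called in the wild type and the double deletion, 3702 moved in the same direction and 89 in opposite directions. MDH2, a cytosolic malate dehydrogenase, fell by 1.12 in the wild type and rose by 1.55 in the double deletion, and the mismatch repair gene MSH6 fell by 1.69 and rose by 0.42. The glucose sensing gene MTH1 rose by 0.94 and fell by 1.38, and the methionine permease gene MUP1 rose by 0.70 and fell by 0.86. These 4 were chosen after their values were seen. MDH2 was already lower in the double deletion than in the wild type at 0 min, so its response difference starts from unequal levels.

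The median response of ribosome biogenesis genes per culture was -1.91 ± 0.22 (SD, n = 3) in the wild type, -1.78 ± 0.23 in the pbf1 deletion, -1.39 ± 0.07 in the pbf2 deletion and -0.75 ± 0.06 in the double deletion. The two-sided exact permutation p against the wild type was 0.5, 0.1 and 0.1, and 0.1 is the smallest that 3 against 3 allows. The median response of cytosolic ribosomal protein genes was -1.88 ± 0.20 (SD, n = 3) in the wild type, -1.84 ± 0.22 in the pbf1 deletion, -1.44 ± 0.09 in the pbf2 deletion and -1.73 ± 0.14 in the double deletion (exact p = 0.8, 0.1 and 0.4). In the authors' deposited table the median log2 ratios of the ribosome biogenesis genes were -2.05, -1.90, -1.54 and -0.77 in the same order.

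**Figure D2:**
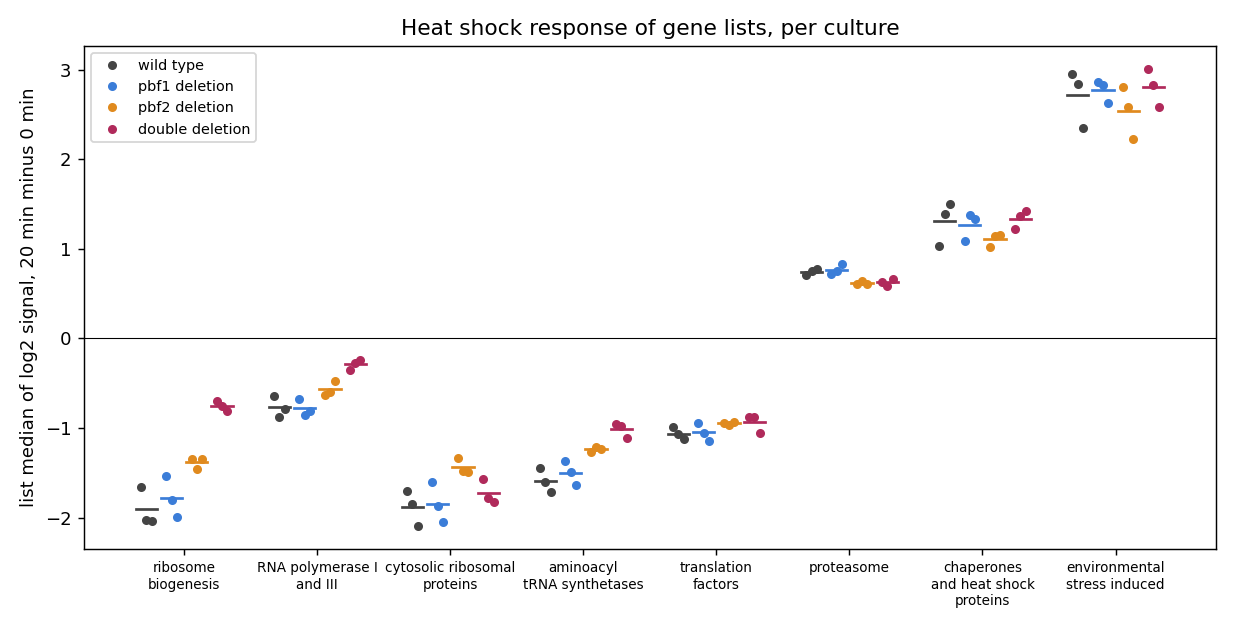
Median log2 change on heat shock of 8 gene lists in each of 3 cultures per strain (points), with the mean as a bar. Ribosome biogenesis genes fell by 1.91 in the wild type and by 0.75 in the double deletion, while the fall of cytosolic ribosomal protein genes was nearest to that of the wild type in the pbf1 deletion.

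In the pbf1 deletion no single gene's heat shock response was called as different. Limma called 0 genes, with 183 at an unadjusted p under 0.05 and a lowest adjusted p of 0.999. The smallest p-values belonged to GRS2 (YPR081C, 0.32 ± 0.09), SSE2 (YBR169C, 0.52 ± 0.15) and BDH1 (YAL060W, 0.61 ± 0.17) on the positive side and to RCK1 (YGL158W, -1.02 ± 0.27), YKL068W-A (-0.59 ± 0.16) and PDC6 (YGR087C, -1.21 ± 0.35) on the negative side, none of which passed. The median difference of the ribosome biogenesis list was 0.10 (camera adjusted p = 0.0171, and 0.895 with an estimated correlation), and that of the environmental stress list 0.12 (0.00214, and 0.864). Sulfur (-0.12), ergosterol (-0.09), cell cycle (-0.09) and mitochondrial ribosomal genes (0.05) also passed camera with the preset correlation (0.448, 0.533, 0.217 and 0.864 with an estimated correlation), and no list passed fry. The positive medians of ribosome biogenesis, stress and mitochondrial ribosomal genes turned negative after spike-in centring, and without the pbf1 deletion's 20 min array of replicate 1 the ribosome biogenesis median was -0.04.

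In the pbf2 deletion some ribosomal protein and ribosome biogenesis genes had a higher response than in the wild type. Of 127 ribosomal protein genes, 24 had a higher response than in the wild type and 0 a lower one (98 and 0 adjusted over the list alone), among them RPL9A (0.90 ± 0.18, adjusted p = 0.0144) and RPS25B (YLR333C, 0.67). Their median difference was 0.46 (camera adjusted p = 5.17e-45, and 0.276 with an estimated correlation, fry 0.0315). Of 164 ribosome biogenesis genes, 10 were higher and 0 lower (48 and 2 adjusted over the list alone), such as the exosome helicase gene MTR4 (YJL050W, 0.94 ± 0.24, adjusted p = 0.0485), FAF1 (YIL019W, 0.83) and KRR1 (YCL059C, 0.64), with a median difference of 0.47 (1.14e-29, 0.276 and fry 0.101). Of 21 aminoacyl tRNA synthetase genes, 4 were higher (11 and 2 lower adjusted over the list alone), such as MES1 (YGR264C, 0.33), with adjusted p = 0.276 with an estimated correlation and 0.0428 by fry. Proteasome genes had a median difference of -0.11 with 0 genes passing (camera 0.00011, estimated 0.276, fry 0.0315), which turned positive after spike-in centring.

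In all, 81 genes responded more positively and 11 more negatively in the pbf2 deletion than in the wild type. The largest positive differences were FAT3 (YKL187C, 1.56 ± 0.23, adjusted p = 0.00116), a fatty acid transport gene, YCT1 (YLL055W, 0.95 ± 0.15), a cysteine transporter gene, MTR4, EFM4 (YIL064W, 0.93 ± 0.13), the importin gene KAP123 (YER110C, 0.92 ± 0.12) and RPL9A (0.90). The largest negative ones were LSO1 (-2.68 ± 0.68, adjusted p = 0.0482), ARG3 (YJL088W, -1.06 ± 0.23), an arginine synthesis gene, NRD1 (YNL251C, -0.86 ± 0.18), a transcription termination gene, the cyclin gene PCL1 (YNL289W, -0.84 ± 0.19), TIR4 (YOR009W, -0.80 ± 0.18) and ATF2 (YGR177C, -0.79 ± 0.17). The count of 92 fell to 25 without the wild type 20 min array of replicate 3 and rose to 332 without that of replicate 1. Without 1 other array it was 48 (wild type 20 min replicate 2), 37, 45 and 41 (wild type 0 min replicates 1 to 3), 47, 46 and 33 (pbf2 deletion 0 min replicates 1 to 3), and 39 and 32 (pbf2 deletion 20 min replicates 1 and 2). Spike-in centring left 0 genes by limma, with 25 at an unadjusted p under 0.05, hybridization control centring left 3 and median centring 53.

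In the double deletion most ribosome biogenesis genes fell less on heat shock than in the wild type: 134 of 164 had a higher response, UTP22 (YGR090W, -0.60) a lower one and 29 did not pass (137 and 1 adjusted over the list alone). The median difference was 1.03 (camera adjusted p = 2.32e-37, and 0.366 with an estimated correlation, fry 0.000173). The pre-ribosome factors FAF1 (2.60 ± 0.16, adjusted p = 2.62e-10), LTV1 (YKL143W, 2.53 ± 0.29), KRE33 (2.30 ± 0.20), YVH1 (YIR026C, 2.29 ± 0.15), KRR1 (2.28 ± 0.11), ENP2 (YGR145W, 2.16 ± 0.20), YTM1 (YOR272W, 2.16 ± 0.25), NUG1 (YER006W, 2.15 ± 0.21) and DHR2 (YKL078W, 2.13 ± 0.28) were among the largest. Of 39 RNA polymerase I and III genes, 13 were higher, RPA49 by 1.55, and TFC7 lower (adjusted p = 0.00458, and 0.525 with an estimated correlation). Of 21 aminoacyl tRNA synthetase genes, 13 were higher, THS1 by 0.92, and 0 lower (16 and 1 adjusted over the list alone; 3.61e-07, and 0.366 with an estimated correlation). Of 48 tRNA modification genes, 20 were higher, TRM1 by 1.90, and 3 lower (22 and 3 adjusted over the list alone; 0.000301, and 0.419 with an estimated correlation). Ribosomal protein genes were mixed, with 46 higher, RPS25B by 0.72, and 4 lower, RPS7B by -0.68 (49 and 6 adjusted over the list alone), a median of 0.16, adjusted p = 0.00427, 0.733 with an estimated correlation and fry 0.172. The median of this list was 0.08 after median centring and 0.02 after spike-in centring. Without the wild type 20 min array of replicate 3 the list's adjusted p was 0.15, and without the double deletion's 20 min array of replicate 1 it was 0.0538.

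Some nucleotide and amino acid genes also had a higher response in the double deletion. URA1, a pyrimidine synthesis enzyme, had the largest difference (2.82 ± 0.14, adjusted p = 6.6e-12), and URA7 (YBL039C, 2.01) and URA4 (YLR420W, 1.69) were among 8 higher and 1 lower of 29 purine and pyrimidine genes (0.0292, and 0.59 with an estimated correlation). URA3, an enzyme gene of uracil synthesis, was on in the double deletion alone. Its part in the pyrimidine differences therefore cannot be separated from the loss of TOD6 and DOT6. Of 58 amino acid synthesis genes, 22 were higher, HIS6 by 1.06, and 4 lower, ARG3 by -1.36 (23 and 5 adjusted over the list alone; 0.000877, and 0.391 with an estimated correlation). Of 37 translation factor genes, 11 were higher, TEF4 by 0.92, and 1 lower (0.0139, and 0.587 with an estimated correlation), with a median of 0.13 that was negative after spike-in centring. Sulfur genes went the other way: 10 of 28 were lower, such as MET32 (YDR253C, -2.17 ± 0.34) and MET28 (YIR017C, -1.98 ± 0.29), and 2 were higher (11 and 2 adjusted over the list alone), with a median of -0.12 and a mean of -0.44 (0.0139, and 0.391 with an estimated correlation). Lower responses also outnumbered higher ones among cell cycle genes (9 and 1, PCL1 by -2.39 ± 0.19), cell wall genes (9 and 2, MKK2 by -0.66), sporulation genes (6 and 0, DMC1 by -1.39), stationary phase genes (5 and 1, SNZ1 by -1.54) and proteasome genes (4 and 1, ADD66 by -0.48). Their camera adjusted p-values were 0.0276, 0.0179, 0.00458, 0.0132 and 0.0071, and lay between 0.366 and 0.391 with an estimated correlation. Adjusted over the list alone, the cell cycle list had 11 lower and 1 higher and the cell wall list 10 and 2, and the other 3 were the same.

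The remaining lists were not called by camera. Stress genes split into 17 higher, SPI1 by 2.26 ± 0.35 and TMA10 by 2.08, and 9 lower, GND2 by -1.88 ± 0.17 and ALD3 by -1.69 (adjusted p = 0.0689). Chaperone genes had 8 higher, SSE2 by 1.28, and 2 lower, trehalose and glycogen genes 3 and 1, glycolysis 1 and 1, respiration 0 and 3, and mitochondrial ribosomal genes 3 and 2. Ergosterol genes had 4 higher and 7 lower, and phosphate and iron genes 7, SIT1 by 1.48, and 4. Haploid and pheromone genes had 4 higher, AGA1 by 1.29, and 0 lower, marker genes 2 and 0, and neighbours of the deleted genes 3 and 2. Adjusted over the list alone these were the same except for trehalose and glycogen genes (2 and 1), respiration (0 and 1), mitochondrial ribosomal genes (2 and 2), phosphate and iron genes (9 and 5) and the neighbours (4 and 2). The medians of the chaperone (0.05), glycolysis (0.10) and neighbour (0.12) lists were negative after spike-in centring, that of the chaperones also after median centring, and the ergosterol median (-0.03) was positive after quantile normalization. The 7 a-cell genes had a median of -0.45 and a mean of 0.00, with ASG7 (YJL170C, 1.11) and AGA2 (YGL032C, 1.08) higher and STE2 (YFL026W, -0.79) lower. Of the alpha-cell genes SAG1 was lower (-0.54). The other named genes were MDH2 (YOL126C, 2.67 ± 0.18) on the positive side and MHT1 (YLL062C, -2.14 ± 0.27), a methionine synthesis gene, on the negative side. Also negative were NRD1 (-2.38 ± 0.18), MTH1 (YDR277C, -2.31 ± 0.56), the pyruvate decarboxylase gene PDC6 (-2.27 ± 0.35), LSO1 (-2.16 ± 0.68), YHR214C-D (-1.98 ± 0.62), ARO10 (-1.96 ± 0.35) and RRT5 (YFR032C, -1.95 ± 0.62). A response difference can also come from the level at 0 min. There MDH2, SPI1 and URA1 were already lower in the double deletion than in the wild type and ARO10 higher, opposite to their response differences. In all, 809 genes had a higher and 689 a lower response, 628 and 1010 after median centring, 795 and 873 after quantile normalization, 469 and 274 after hybridization control centring and 4 and 2 after spike-in centring.

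**Figure D3:**
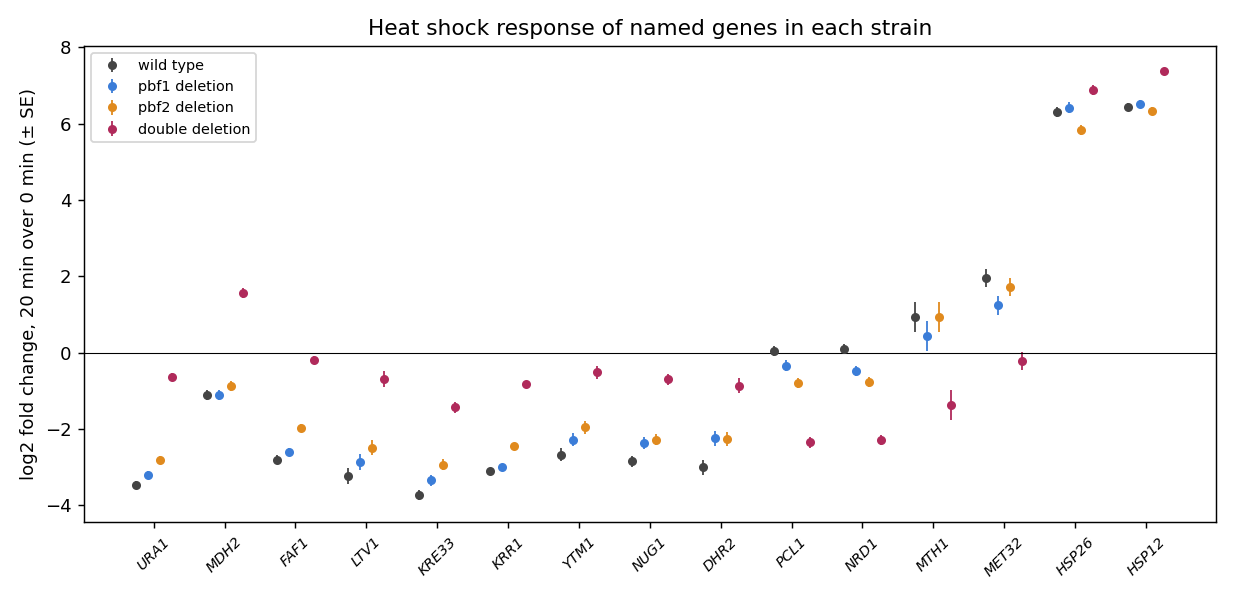
Log2 change on heat shock ± SE of 15 named genes in the 4 strains. KRR1, FAF1 and URA1 fell less in the double deletion than in the other strains, by 2.28, 2.60 and 2.82 against the wild type. URA3 was on in the double deletion alone, so its part in the URA1 difference cannot be separated.

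Against the pbf1 and pbf2 deletions, 123 and 80 of 164 ribosome biogenesis genes had a higher response in the double deletion. Compared with the pbf1 deletion, 681 genes had a higher and 636 a lower response (550 and 876 after median centring, 324 and 209 after hybridization control centring, 3 and 0 after spike-in centring), led by MDH2 (2.68), URA1 (YKL216W, 2.57), FAF1 (2.41), KRR1 (2.18), LTV1 (2.17) and MSH6 (YDR097C, 2.03). The largest negative differences were YHR214C-E (-3.07), PCL1 (-2.01), ALD3 (-2.00), YDL114W (-1.92), YOR032W-A (-1.87) and GND2 (YGR256W, -1.82). Of 164 ribosome biogenesis genes, 123 were higher and 0 lower (135 and 1 adjusted over the list alone; median 0.94, adjusted p = 3.55e-38, and 0.334 with an estimated correlation). Ribosomal protein genes had 26 higher and 4 lower (24 and 4 adjusted over the list alone; 0.0143, and 0.796 with an estimated correlation). Compared with the pbf2 deletion, 606 genes were higher and 514 lower (443 and 681 after median centring, 202 and 187 after hybridization control centring, 0 and 6 after spike-in centring), led by MDH2 (2.44), TMA10 (2.28), YRO2 (YBR054W, 2.22), SPI1 (YER150W, 2.20), URA1 (2.17) and YGP1 (YNL160W, 2.07), and by MTH1 (-2.31), ARO10 (-2.16), ALD3 (-2.11), MHT1 (-2.06), MET2 (YNL277W, -2.04) and PDC6 (-2.01). Here 80 ribosome biogenesis genes were higher and 1 lower (95 and 1 adjusted over the list alone; median 0.58, 1.1e-18, and 0.631 with an estimated correlation). In contrast, 48 ribosomal protein genes, such as RPL33B (YOR234C, -1.44) and RPL13A (-1.43), were lower and 5 higher (53 and 7 adjusted over the list alone; median -0.20, 2.08e-06, and 0.631 with an estimated correlation). After spike-in centring the medians against the pbf2 deletion were 0.164 for ribosome biogenesis and -0.623 for ribosomal protein genes. Among the leading genes, MDH2, URA1, SPI1, YRO2 and YGP1 were lower in the double deletion than in the wild type at 0 min.

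The response of the double deletion departed from the sum of the single deletions in part of both ribosomal groups. Of 164 ribosome biogenesis genes, 20 lay above the sum and 0 below (41 and 1 adjusted over the list alone), FAF1 by 1.58 and KRR1 by 1.53, and a median of 0.51 (adjusted p = 1.41e-15, and 0.643 with an estimated correlation, fry 0.2). Of 127 ribosomal protein genes, 15 lay below it and 0 above (34 and 0 adjusted over the list alone), RPL33B by -1.58 ± 0.36, and a median of -0.31 (3.84e-09, 0.643 and fry 0.245). Chaperone genes had 4 higher, SSE2 by 0.98 and HSP12 by 0.96 (0.000796, and 0.643 with an estimated correlation). Over all genes 128 were higher and 100 lower (101 and 135 after median centring). The largest positive departures were MDH2 (2.44 ± 0.26), URA1 (1.92 ± 0.19), SPI1 (1.89 ± 0.49), YGP1 (1.88 ± 0.22), YRO2 (1.83 ± 0.38) and JJJ3 (YJR097W, 1.64 ± 0.33). The largest negative ones were RPL33B, ALD3 (-2.43 ± 0.39), MET2 (-1.79 ± 0.45), MET28 (-1.76 ± 0.40), GND2 (-1.64 ± 0.23) and MHT1 (-1.60 ± 0.39). Of the positive ones, MDH2, URA1, SPI1, YGP1 and YRO2 were already lower in the double deletion than in the wild type at 0 min. Their departures therefore start from unequal levels. For URA1 the part of URA3, which was on in the double deletion alone, cannot be separated either. The count of 228 was 114 without the pbf1 deletion's 20 min array of replicate 2, and 143 and 140 without the pbf2 deletion's 20 min arrays of replicates 2 and 3. Hybridization control centring left 8 genes, and spike-in centring 0 by limma, with 28 at an unadjusted p under 0.05.

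Before heat shock the single deletions differed from the wild type in few genes. In the pbf1 deletion 2 genes were higher and 4 lower: the ribosome biogenesis gene KRR1 (0.42 ± 0.08) and CFD1 (YIL003W, 0.37 ± 0.06) were higher, and the sulfur genes STR2 (YJR130C, -1.43 ± 0.08) and MET3 (YJR010W, -0.50 ± 0.09), the silencing gene SIR2 (YDL042C, -0.53 ± 0.10) and TOD6 lower. In the pbf2 deletion 11 genes were higher and 2 lower, and 5 of the higher ones are iron uptake genes: FIT1 (YDR534C, 1.35 ± 0.24, adjusted p = 0.0218), FIT2 (YOR382W, 1.12 ± 0.21), ARN2 (YHL047C, 1.09 ± 0.14), SIT1 (YEL065W, 0.85 ± 0.17) and ARN1 (YHL040C, 0.67 ± 0.09). The phosphate and iron list had 5 higher genes (9 adjusted over the list alone), a median of 0.27 and adjusted p = 1.58e-13, and held with an estimated correlation (0.00161). The list median was 0.03 after spike-in centring. COS12 (YGL263W, -1.32 ± 0.27) and DOT6 were lower. The pbf2 counts were 4 and 1 after quantile normalization and after hybridization control centring, 7 and 2 after median centring and 0 and 2 after spike-in centring. The pbf1 counts were 2 and 2, 0 and 2, 3 and 4, and 0 and 1 in the same order. Without the wild type array of replicate 2 the pbf1 count was 2, and without single arrays the pbf2 count was 4 (wild type replicate 1, wild type replicate 3, pbf2 deletion replicate 3) or 3 (pbf2 deletion replicate 2). The ribosome biogenesis list had a median of 0.19 in the pbf1 deletion (1.79e-28, and 0.373 with an estimated correlation).

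The double deletion already differed before heat shock in part of the ribosome biogenesis, mating and mitochondrial genes. Of 164 ribosome biogenesis genes, 71 were higher and 0 lower (93 and 0 adjusted over the list alone), DHR2 by 0.99 and KRR1 by 0.81, with a median of 0.40 (8.05e-26, and 0.317 with an estimated correlation). Of 48 tRNA modification genes, 20 were higher and 0 lower, TAD2 by 0.80 (24 and 0 adjusted over the list alone; 4.85e-09, and 0.229 with an estimated correlation). Of 39 RNA polymerase I and III genes, 10 were higher and 2 lower (12 and 2 adjusted over the list alone; 6.94e-05, and 0.334). Of 66 genes of the mitochondrial ribosomal protein list, 49 were lower and 0 higher, MRPL6 by -0.36 (55 and 0 adjusted over the list alone; 2.57e-14, and 0.0729 with an estimated correlation), with a median of -0.28 that turned positive after spike-in centring. Of 14 haploid and pheromone genes, 7 were lower, PRM1 by -1.60, AGA1 by -1.55 and FIG1, which was at background on every array there (10 adjusted over the list alone; 9.86e-06, and 0.101 with an estimated correlation). Of 7 a-cell genes, 3 were lower, AGA2 by -2.35 ± 0.27, ASG7 by -2.12 ± 0.13 and MFA1 by -1.54 ± 0.19 (0.000889, and 0.297). Of 23 phosphate and iron genes, 10 were lower, PHO5 by -1.96 (0.000303, and 0.101).

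Part of the stress and sulfur genes were also lower in the double deletion at 0 min. Of 93 stress genes, 40 were lower, YGP1 by -2.05, SPI1 by -2.06 and HSP12 by -1.02, and 3 higher (54 and 3 adjusted over the list alone; 1.83e-09, and 0.387 with an estimated correlation). Of 21 trehalose and glycogen genes, 9 were lower and 1 higher (14 and 1 adjusted over the list alone; 0.00565, and 0.567). Of 28 sulfur genes, 11 were lower, STR2 by -1.48 and MET6 by -1.31, and 1 higher (12 and 3 adjusted over the list alone; 0.00565, and 0.297). Of 8 neighbours of the deleted genes 5 were lower, MET6 among them (0.00768, and 0.1). The medians of the sulfur (-0.18) and neighbour (-0.26) lists were positive after spike-in centring. Among genes above background in both groups, the largest differences outside the markers were ARO10 (2.15 ± 0.25), YDL218W (1.59 ± 0.36), YNL162W-A (1.52 ± 0.22), SIL1 (YOL031C, 1.41 ± 0.20) and YAR009C (1.38 ± 0.48, a probe set shared between transcripts). On the lower side they were MDH2 (-2.49 ± 0.13), AGA2, YRO2 (-2.23 ± 0.19), CIS1 (YLR346C, -2.23 ± 0.23) and FMP48 (YGR052W, -2.21 ± 0.19). Signals of the pyrimidine genes URA1 and URA4 were 2741 and 1728 in the double deletion at 0 min and 7565 and 3037 in the wild type. Here too the part of URA3, on in the double deletion alone, cannot be separated. In all, 457 genes were higher and 862 lower, 446 and 523 after quantile normalization, 630 and 651 after median centring, 220 and 250 after hybridization control centring, and 9 and 14 after spike-in centring.

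After heat shock, 5 of 164 ribosome biogenesis genes were higher than in the wild type in the pbf1 deletion, 81 in the pbf2 deletion and 153 in the double deletion. In the pbf1 deletion 15 genes were higher and 19 lower (23 and 18 after median centring, 46 and 39 after quantile normalization, 1 and 2 after hybridization control centring, 0 and 1 after spike-in centring). The higher ones included DHR2 (1.17 ± 0.20), NUG1 (0.71 ± 0.15), ENP2 (0.69 ± 0.14), FAF1 (0.59 ± 0.11) and YHL009W-B (0.84 ± 0.19, a probe set shared between transcripts). The lower ones included STR2 (-1.10 ± 0.08), the glucose transporter gene HXT1 (YHR094C, -0.70 ± 0.14), YKL068W-A (-0.65 ± 0.11), MET3 (-0.63 ± 0.09) and UBP11 (YKR098C, -0.52 ± 0.12). The ribosome biogenesis list had 24 higher genes adjusted over the list alone and a median of 0.31 (4.51e-36, and 0.276 with an estimated correlation). Sulfur genes had 4 lower (12 adjusted over the list alone) and a median of -0.29 (2.27e-10), and held with an estimated correlation (0.0214). The count of 34 was 122 without the wild type array of replicate 1, 13 and 11 without those of replicates 2 and 3, and 16 and 13 without the pbf1 arrays of replicates 1 and 2.

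In the pbf2 deletion after heat shock, 466 genes were higher and 249 lower (396 and 439 after median centring, 311 and 18 after hybridization control centring, 0 and 1 after spike-in centring). Ribosome biogenesis genes had 81 higher, DBP3 by 1.14 ± 0.23 and MTR4 by 0.98, and 2 lower, DBP2 by -0.81 (112 and 2 adjusted over the list alone; 5.66e-29, and 0.298 with an estimated correlation). Ribosomal protein genes had 75 higher, RPL4B by 1.08 ± 0.25, and 1 lower (98 and 3 adjusted over the list alone; 2.44e-27, and 0.298). Chaperone genes had 12 lower and 2 higher (22 and 2 adjusted over the list alone; 8.8e-08, and 0.298) and proteasome genes 11 lower and 0 higher, PUP1 by -0.26 (17 and 1 adjusted over the list alone; 1.81e-07, and 0.251). The largest differences were FAT3 (1.401 ± 0.17), DBP3, SRO77 (YBL106C, 1.12 ± 0.19), RPL4B and YGR174W-A (1.06 ± 0.28, a shared probe set), and COS12 (-1.51 ± 0.27), YOR072W-B (-1.26 ± 0.28, a shared probe set), YKL183C-A (-1.05 ± 0.29), NRD1 (-0.91 ± 0.13) and SPO16 (YHR153C, -0.88 ± 0.20). The count of 715 was 280 without the wild type array of replicate 3, and 380 and 453 without the pbf2 arrays of replicates 1 and 2.

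In the double deletion after heat shock, 1130 genes were higher and 1750 lower (1082 and 862 after hybridization control centring, 270 and 48 after spike-in centring). Ribosome biogenesis genes had a median of 1.49 (153 and 1, 154 and 1 adjusted over the list alone; 5.28e-51, and 0.2 with an estimated correlation), led by FAF1 (3.30 ± 0.11), DHR2 (3.12 ± 0.20), LTV1 (3.09 ± 0.20), KRR1 (3.08 ± 0.08) and YVH1 (2.97 ± 0.11). Of 48 tRNA modification genes 29 were higher and 4 lower (6.09e-09, and 0.207), of 21 synthetase genes 15 higher and 0 lower (9.03e-08, and 0.207), and of 127 ribosomal protein genes 57 higher and 14 lower (0.000201, and 0.653). Sulfur genes had 18 lower and 0 higher, STR3 by -2.10 (0.000336, and 0.2), mitochondrial ribosomal genes 49 lower and 0 higher, MRPL19 by -0.62 (5.92e-07, and 0.2), cell cycle genes 22 lower and 3 higher (0.00381, and 0.2), and a-cell genes 7 lower of 7, MFA2 by -0.96 (0.00689, and 0.339). Adjusted over the list alone, the synthetase list had 16 higher, the sulfur list 18 lower and 2 higher and the mitochondrial list 53 lower, and the other lists were the same. Of the other lists, 20 proteasome genes were lower and 0 higher (0.0303, and 0.461), with a median of -0.15 that was positive after spike-in centring, 10 sporulation genes lower and 0 higher (0.0181, and 0.207), and 8 stationary phase genes lower and 1 higher (0.0303, and 0.272). The largest falls against the wild type were YHR214C-D (-2.69 ± 0.44), the meiotic cohesin gene REC8 (YPR007C, -2.53 ± 0.99), BAG7 (YOR134W, -2.52 ± 0.56), PCL1 (-2.46 ± 0.14) and MET28 (-2.38 ± 0.20).

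Many genes that differed in response or after heat shock in a single deletion differed in the double deletion too. Of the 81 genes with a higher response in the pbf2 deletion, 66 were also higher in the double deletion (12.2 if independent), and of the 11 lower ones 9 were also lower (1.4 if independent). All 15 genes higher after heat shock in the pbf1 deletion were higher in the double deletion (3.14 if independent), and 16 of the 19 lower ones were lower (6.16). For the pbf2 deletion after heat shock, 350 of 466 higher genes (97.6 if independent) and 132 of 249 lower ones (80.8) were shared with the double deletion. At 0 min 1 of 11 higher genes of the pbf2 deletion (0.93 if independent) and 1 of 2 lower ones (0.32) were shared. That shared lower gene was DOT6, which is deleted in both strains. The shared lower genes after heat shock likewise include TOD6 for the pbf1 deletion and DOT6 for the pbf2 deletion. All of these comparisons share the wild type arrays. Across genes, which are not independent replicates, the response differences of the pbf2 and double deletions correlated with r = 0.515, against a median of 0.441 (0.013 to 0.773) in simulated unchanged groups sharing controls, with a covariance of 0.0779 against 0.0265. After heat shock r with the double deletion was 0.624 against 0.454 (-0.212 to 0.953) for the pbf1 deletion and 0.528 against 0.469 (-0.64 to 0.898) for the pbf2 deletion, with covariances of 0.0817 against 0.0134 and 0.0924 against 0.0117. All of these r lay inside the simulated ranges. The other pairs lay below the simulated medians: the response differences of the pbf1 deletion with those of the double deletion (0.401 against 0.454, covariance 0.0443 against 0.0286) and of the pbf2 deletion (0.37 against 0.548, 0.0226 against 0.0318). At 0 min the pbf2 deletion had 0.251 against 0.438 with the double deletion (0.0218 against 0.0148) and 0.251 against 0.556 with the pbf1 deletion (0.0113 against 0.0174). After heat shock the single deletions had 0.437 against 0.59 (0.025 against 0.0147).

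Over all comparisons, camera with an estimated correlation kept the phosphate and iron list in the pbf2 deletion at 0 min and the sulfur list in the pbf1 deletion at 20 min, and no other list. Fry, which asks whether a list moves one way without reference to other genes, passed 26 of 26 lists for heat shock in the wild type, 16 for the response difference of the double deletion, 3 for that of the pbf2 deletion and 0 for that of the pbf1 deletion.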

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

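The 3 tests on the poly(A) spike-in controls and the spike-in centring were chosen only after the results were seen here. The tests of the ribosomal lists and the other splits of the samples were set before.

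Of 164 ribosome biogenesis genes, 134 had a higher response to heat shock in the double deletion than in the wild type, with a list median difference of 1.031 (log2, adjusted p = 0.366 with an estimated correlation), and 1498 genes differed in response. A weaker response of all genes would leave no difference once each culture's slope on the pbf1 deletion response is removed, and of the 1.155 (SD 0.16) between the culture medians 0.976 (SD 0.173) was left, with the 3 cultures of the double deletion at 0.628 to 0.864 and those of the wild type at -0.405 to 0.015. The culture medians differed by 1.227 (SD 0.187) after quantile normalization and by 1.073 (SD 0.173) after median centring, which argues against these scalings of the arrays as the whole cause. The lowest difference came after spike-in centring, 1.013 (SD 0.749, exact permutation p = 0.2), and 0.89 for the fitted list median. It stayed above its SD, as the rule set before asked, but the spread is too wide for that centring to decide alone. The joint loss of 2 PAC-binding repressors is a biological explanation that the design names, and it may account for the pattern, as a hypothesis that was not tested here. URA3 was on in the double deletion alone and follows the same groups, so its part cannot be separated.

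In the pbf2 deletion 10 of 164 ribosome biogenesis genes (fitted list median difference 0.472, fry 0.101) and 24 of 127 cytosolic ribosomal protein genes (0.460, fry 0.0315) had a higher response than in the wild type (adjusted p = 0.276 for each list with an estimated correlation), and 92 genes differed in response. For ribosome biogenesis the culture medians differed by 0.521 (SD 0.162), of which removing the slope left 0.346 (SD 0.163). The deletion cultures then lay at 0.053 to 0.233 and the wild type cultures at -0.405 to 0.015. This is just past the 2 SD of the rule set before, so it argues only narrowly against a weaker response of all genes as the whole cause. Quantile normalization left 0.505 (SD 0.184) and median centring 0.504 (SD 0.165, and 0.455 for the fitted list median). Leaving out 1 wild type array after heat shock left a fitted list median of at least 0.335 (replicate 3). These values argue against these scalings and a single wild type array as the whole cause. After spike-in centring the ribosome biogenesis difference was 0.80 with a wider spread (SD 0.571), too wide for that centring to decide alone. For ribosomal proteins the culture medians differed by 0.447 (SD 0.152). They differed by 0.447 (SD 0.152) after quantile normalization and by 0.430 (SD 0.169) after median centring, which argues against these scalings as the whole cause. The spread was widest after spike-in centring (0.726, SD 0.606, exact permutation p = 0.2), too wide for that centring to decide alone. After removal of the slope 0.342 (SD 0.195) was left, with deletion cultures at -0.001 to 0.344 and wild type cultures at -0.407 to -0.004. This is under 2 SD of the cultures, which were not paired by number, so by the rule set before a weaker response of all genes stays open. Taken by replicate number, the deletion lay higher each time: 0.3435 against -0.0042, 0.1975 against -0.076, and -0.0014 against -0.4072. If equal numbers share a batch, which the labels do not name, these values argue against a weaker response of all genes as the whole cause. Loss of DOT6 may explain the ribosome biogenesis part, as a hypothesis.

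The poly(A) spike-in controls, which lie outside the main measurement, rose after heat shock in 12 of 12 cultures, by 0.564 to 1.948 (log2). Degraded RNA after heat shock stays open, since the 3' over 5' ratio of 7 yeast control genes had a highest median rise of 0.095 but went both ways, up to 0.616 for EAF5 (higher in 10 of 12 cultures) and down to -0.684 for TDH1. The rise exceeded that of the hybridization controls by at least 0.310, and by more than 0.4 in 11 cultures, so the scaling may explain part of it and stays open. Unequal amounts of spike-in could also explain it and stay open, with an SD of 0.529 over the cultures. A lower share of messenger RNA in total RNA after heat shock would give the same sign and was not tested.

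The other differences between groups are given as values. The response differed in 1317 genes between the double and pbf1 deletions and in 1120 between the double and pbf2 deletions, and 228 genes departed from the sum of the single deletions. The ribosome biogenesis list differed by 0.098 in the pbf1 deletion and the ribosomal protein list by 0.162 in the double deletion. Of 89 genes that passed in opposite directions in the wild type and the double deletion, all 89 also passed the test of the response difference. Both responses come from 1 fit with equal standard errors, so 2 opposite calls fix this outcome in advance. It is no further evidence. Of the 89 genes, 37 fell in the wild type and rose in the double deletion, 2 of them ribosome biogenesis genes, and 52 did the reverse.

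Signals in control probe sets that the comparisons do not use were also seen. Of 47 reporter probe sets, 1 was above background in every deletion strain and on no wild type array, with a lowest group mean of 13.432 (log2). The URA3 control probe sets had a mean of 10.125 in the double deletion before heat shock. The 25S rRNA probe sets rose in every culture, by at least 1.750.

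Splits of the same arrays into groups of 3 number 10 with the real one, too few for a share under 0.05. Only 1 split, the real one, reached the real count for heat shock in the wild type (4352, highest other 0), the pbf1 deletion (4403, 0), the pbf2 deletion (4235, 0) and the double deletion (4282, 1). The other splits for heat shock put 0 min and 20 min arrays in the same group. Large heat shock changes then enter the spread, so their low counts were to be had whatever the noise. The same 1 of 10 held for the response differences of the pbf2 deletion (92, highest other 0) and the double deletion against the wild type (1498, 0), the pbf1 deletion (1317, 0) and the pbf2 deletion (1120, 0). It also held at 0 min for the pbf1 deletion (6, highest other 1), the pbf2 deletion (13, 0) and the double deletion (1319, 3), and at 20 min for the pbf2 deletion (715, 0) and the double deletion (2880, 26). For the response difference of the pbf1 deletion, where limma called 0 genes and 183 had an unadjusted p under 0.05, all 10 splits reached 0, with 3 as the highest other. At 20 min 2 of 10 splits gave as many genes as the 34 of the pbf1 deletion. The other gave 605 and set wild type 1, pbf1 1 and pbf1 2 against wild type 2, wild type 3 and pbf1 3, which points to a structure of the samples other than strain. For the departure from the sum, 3 of 100 splits gave at least 228 genes, the real one included, a share under 0.05. The highest other gave 614. These splits mix cultures of all strains, so a culture of the double deletion can carry the label of another strain. Since 1498 genes differed in response between the double deletion and the wild type, a count such as 614 can come from strain itself. The share is set against no difference between any strains, so it cannot decide whether the single deletions add up.

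Part of the overlap between strain differences may come from the shared wild type arrays, which number 3 and cannot be split into 2 sets of 2. The response differences of the pbf2 and double deletions correlated with r = 0.515 across genes, which are not independent replicates, and simulated unchanged groups gave a median of 0.441. Of 81 higher responses in the pbf2 deletion 66 were shared, and without the wild type array of replicate 3 after heat shock the pbf2 count was 25.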

How the results depend on the processing

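Alternatives chosen only after the results were seen were spike-in and hybridization control centring, the replicate number within each time as a block (and the replicate number for response differences), shared probe sets left out, correlations under other filters, and list tests and list medians with replicates left out. Where values below moved, the cause was not tested unless the sentence gives it.

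Within 1.5 times of the reported value were 154 of 208 counts of genes and 148 of 170 counts of lists over the alternatives that use all arrays. Of 7107 values of named genes, 6514 kept their side of the threshold, and those of them that passed also kept their direction. A further 573 fell short of it, 18 passed it anew and 2 passed in the reverse direction. Changes of sign in values that did not pass were not counted. Of 4340 single list tests, 3874 kept their side by the same rule, 351 fell short and 115 passed anew. No count of genes moved by more than 1.5 times without a filter, with a pseudocount of 50, without shared probe sets or with the culture as a block.

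The estimated correlation left 0 lists in 14 comparisons and 1 each in the pbf1 deletion after heat shock and the pbf2 deletion before it. For response differences it gave the ribosome biogenesis list adjusted p-values of 0.895 (pbf1), 0.276 (pbf2), 0.366 (double), 0.334 (double against pbf1), 0.631 (double against pbf2) and 0.643 (departure from the sum). It gave the ribosomal protein list 0.276 (pbf2), 0.733 (double), 0.796 (double against pbf1), 0.631 (double against pbf2) and 0.643 (departure).

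Spike-in centring gave 2490 genes for heat shock in the wild type and 1885 in the pbf2 deletion. By limma it left 0 genes for the response difference of the pbf2 deletion (25 at an unadjusted p under 0.05), 6 for the double deletion, 3 for double against pbf1, 6 for double against pbf2 and 0 for the departure (28 unadjusted). It left 1, 2 and 23 before heat shock and 1, 1 and 318 after it in the pbf1, pbf2 and double deletions. The lists passing before heat shock were 5 and 3 in the pbf1 and pbf2 deletions, and the ribosomal protein test was 0.156 (double) and 0.326 (double against pbf1). The ribosomal protein median response differed from the wild type by -0.185 (pbf1) and 0.726 (pbf2), and that of ribosome biogenesis by 0.80 (pbf2). ASG7 in the pbf1 deletion reversed to -0.911.

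Hybridization control centring gave response differences of 3 (pbf2), 743 (double), 533 (double against pbf1) and 389 (double against pbf2) genes and 8 for the departure. It gave 2, 5 and 470 before heat shock in the pbf1, pbf2 and double deletions, and 3 and 329 after it in the pbf1 and pbf2 deletions. Median centring gave 53 genes for the pbf2 response difference. Quantile normalization gave 85 genes for pbf1 after heat shock, 5 genes and 6 lists for pbf2 before it, 7 lists for the departure, 0.0167 for the ribosomal protein test of the pbf1 response, and reversed HXK2 in the wild type heat shock to 0.125.

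The stricter filter tests fewer genes by construction. It gave 2319, 2354, 2268 and 2316 genes for heat shock in the wild type, pbf1, pbf2 and double deletions. It gave 885, 773 and 684 for the response of the double deletion against the wild type, pbf1 and pbf2. In the double deletion it gave 734 before and 1493 after heat shock. Before heat shock it left 0 genes by limma in the pbf1 deletion (187 at an unadjusted p under 0.05) and 8 in the pbf2 deletion. The lists passing were 9 (double) and 7 (double against pbf1), with list tests of 0.0559 and 0.116 for ribosomal proteins and 0.0565 for ribosome biogenesis in the pbf1 response. Across genes, which are not independent replicates, responses correlated with r = 0.9287 (wild type and double), 0.9879 (pbf1 and pbf2), 0.9416 (pbf1 and double) and 0.9447 (pbf2 and double).

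Fits of only the groups compared use fewer samples by construction and gave 58 genes for the pbf2 response, 3 and 8 before heat shock and 2 and 183 after it in the pbf1 and pbf2 deletions. Fits using eBayes without trend gave 59 for the pbf2 response and 6 for pbf2 before heat shock. A pseudocount of 50 gave list tests of the pbf1 response of 0.0368 (ribosomal proteins) and 0.0654 (ribosome biogenesis).

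Replicate numbers were shared across strains, and at 12 of 12 arrays after heat shock and 11 of 12 before it the most similar residuals of another strain carried the same number, a hint of a common structure that the labels do not name. With the replicate number as a replicate block, 264 genes differed in the pbf2 response, 402 departed from the sum and 107 differed after heat shock in the pbf1 deletion. With the replicate number within time as a replicate block these were 526, 754 and 236, with 1725 for double against pbf2, 28 and 37 before heat shock in the pbf1 and pbf2 deletions, 1329 after it in the pbf2 deletion and 0.0495 for the ribosomal protein test of the pbf1 response.

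With 1 array left out, counts of genes ranged from 25 (wild type 20 min replicate 3) to 332 (replicate 1) for the pbf2 response, 114 (pbf1 20 min replicate 2) to 286 (replicate 1) for the departure. They ranged from 2 (wild type 0 min replicate 2) to 7 for pbf1 and 3 (pbf2 0 min replicate 2) to 9 for pbf2 before heat shock. After it they ranged from 11 (wild type 20 min replicate 3) to 122 (replicate 1) for pbf1 and 280 (wild type 20 min replicate 3) to 1057 (replicate 1) for pbf2. Other gene counts stayed within 1.5 times, such as 1321 to 1500 for the double deletion's response. Lists passing ranged from 5 to 10 (pbf1 response), 11 to 16 (double), 9 to 15 (double against pbf1), 5 to 14 (departure), 7 to 14 (pbf1 before heat shock), 7 to 13 (pbf2 before) and 14 to 18 (double after). The ribosome biogenesis test of the pbf1 response ranged from 2.34e-16 to 0.27 and reversed at 0.0484 without pbf1 20 min replicate 1, and ribosomal protein tests ranged from 6.49e-10 to 0.879 (pbf1 response), 4.59e-06 to 0.15 (double) and 0.000208 to 0.301 (double against pbf1). The ribosome biogenesis test of the double deletion's response ranged from 1.06e-47 to 3.82e-32.

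A planned test of genes with a PAC motif upstream was not run, since it needs a genome sequence that was not used here. Signal over background limits 18 genes that were above background on no array, and the 54 genes left out were not tested.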

Other observations

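No hypothesis beyond those above was tested in this part, and the values below were chosen only after the results were seen.

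The rRNA probe sets rose on heat shock by amounts that varied between cultures. The 25S probe sets rose by 4.82 ± 1.02 (log2, SD, n = 3) in the wild type, 4.83 ± 1.504 in the pbf1 deletion, 2.83 ± 0.64 in the pbf2 deletion and 3.05 ± 1.68 in the double deletion, with two-sided exact permutation p of 0.9, 0.1 and 0.2 against the wild type. The 18S probe sets rose by 2.76 ± 0.87, 3.27 ± 1.06, 1.36 ± 0.18 and 0.96 ± 2.10 (exact p = 0.6, 0.1 and 0.3), and in 1 culture of the double deletion they fell by 1.20. The 5.8S probe set rose by 1.568 ± 0.105, 1.423 ± 0.66, 0.864 ± 0.34 and 1.019 ± 0.525 in the same order (exact p = 0.9, 0.1 and 0.1). With 3 cultures against 3 the exact p cannot go below 0.1.

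In the authors' deposited table the median log2 ratios of the cytosolic ribosomal protein genes were -1.73 in the wild type, -1.66 in the pbf1 deletion, -1.14 in the pbf2 deletion and -1.46 in the double deletion. In the authors' deposited table the log2 ratios lay below the fitted changes by a median of -0.19, -0.19, -0.16 and -0.22 in the same order.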
